A study of Mus musculus with 6 samples.

How the data were processed

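Sequencing libraries were made from total RNA of 661W cells extracted with TRIzol, using a dual-mode mRNA library kit (Hieff NGS Ultima), per the labels' protocols. There were 6 libraries, 3 of the Light group and 3 of the Dark group, and every library's group and number were taken from its title. Reads were processed with HISAT2 against mm10, per the submitters' processing notes, which give no version. The program that computed FPKM, its gene annotation, the read strand setting and the read depth are not given in the sources used here. The authors deposited FPKM per gene, per the file headers, once as a table of the whole series and once per sample. Both held the same values in all 24879 lines.

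The table named 22036 genes by Ensembl identifier and 2843 by the authors' own new-gene numbers. Coordinates, transcript lengths and GC content came from GENCODE release M21 on the same build, in which 22022 identifiers were found and 14 were not. Length and GC content are those of each gene's longest annotated transcript, which need not be the one expressed. Gene symbols that a spreadsheet had turned into dates (27) were restored from their identifiers. A total of 5579 lines stood at 0 in every library. The low values were checked for whole-read steps, and the commonest ratio between libraries was shared by only 1.21% to 1.93% of 827 low genes, so reads could not be recovered. Precision therefore rests on the spread between 3 libraries per group alone. An exact 0 is reported as listed at 0, and no fold change is given against a group at 0.

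Tests were planned for read counts or for FPKM, and the plan for FPKM was used. Genes with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1), with a pseudocount of 1, by limma 3.58.1 in R 4.3.3 (eBayes with trend and robust options, 2-sided), with group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 45 gene lists, the 16 fixed genes, the test, the naming rule and most alternatives were set before the data were examined. Lists with at least 3 tested members were compared with all other genes by camera at a preset correlation of 0.01, adjusted over the 39 lists tested, and again with an estimated correlation and by fry. Members were also adjusted over the list alone. To set a list beside genes of like kind, each member was exchanged for a gene outside the list, in 10000 draws. That gene was one of the member's 50 nearest in transcript length, GC content and mean FPKM. Unlisted genes of the same family could serve as matches.

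The genes named are the 10 largest increases and the 10 largest decreases past the threshold, with a symbol that is not a clone or predicted-gene name, a mean of at least 5 FPKM and groups that do not overlap. To these are added up to 3 called members with the smallest p-values of each called list, up to 2 of every other list with at least 3 called members, and 16 fixed genes. Single exceptions within a list, paralogs and pseudogenes, Cdk1, Ccnb1, and the markers Cd68, Flt1, Rgs9, Rdh5, Rdh10, Glul, Slc1a3, Cry1 and Cry2 were named after their values were seen. Some genes that the rule gives are not reported.

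The alternatives were no filter on low values, a mean of at least 5 FPKM, quantile normalization, median centring, a pseudocount of 0.1, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. After the data were seen 4 more were added: rescaling each library to the same FPKM total, as in TPM, removing from each library a loess trend (span 0.5) with transcript length and GC content, the main axis of differences within groups as a covariate, and a fit without Dark 1 and Light 2. A linear slope of all genes' changes on the mean of Dark 1 minus Dark 2 and Light 1 minus Light 2 was also taken out of list medians and of Mki67.

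The procedure was tested on simulated data for the comparison of Light with Dark, with 200 changed genes among 11068. Of 67 genes changed by a log2 value of 0.5 it recovered 53.7%, of 67 changed by 1 it recovered 98.5%, and of 66 changed by 2 it recovered 100%, with 8 false calls among 176. A simulated list raised by 0.5 was called, and 0 of the others. The simulated noise was drawn separately for each gene, so variation shared by list members was left out. In the measured lists the estimated correlation between members ran from -0.40 to 0.80. The list simulation therefore cannot show how often camera with its preset correlation calls real lists falsely. The matched comparison, run on the ribosomal protein list, returned 0.06 with no shift and 0.56 for a shift of 0.5. With no shift the list already lay at percentile 91.6 of the matched draws.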

Results

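Messenger RNA of 661W cells, an immortalised mouse line derived from cone photoreceptors, was compared between illuminated and unlit cultures, to ask which transcripts differ. The Light group (3 libraries) stood under a cold white fluorescent lamp at 2000 ± 100 lux for 24 h, and the Dark group (3 libraries) was kept unlit for the same 24 h. The deposited values are FPKM (fragments scaled by transcript length and library size), which summed to 420934 ± 12025 per Dark library and 464998 ± 6164 per Light library (SD, n = 3 each). No read totals come with them, so the sequencing depth behind each value is unknown and no counting interval is given. Nothing in the labels says that the replicates were separate cultures. The p-values therefore measure the spread between these samples, which may be technical. Fold changes are Light over Dark on the log2(FPKM + 1) scale, which understates the change of genes with low values, and adjusted p-values are from limma with Benjamini-Hochberg adjustment unless another test is named.

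Light-exposed cells carried more mRNA for NRF2 targets and for the amino acid stress response, and less mRNA for collagens and other matrix proteins. The list tests behind this passed with camera's preset correlation but not with an estimated one (adjusted p = 0.221 to 0.241). Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, rose from 135 ± 12.9 to 656 ± 50.7 FPKM (SD, n = 3), a log2 change of 2.27 ± 0.09 (SE; adjusted p = 4.13e-05). Trib3, a pseudokinase gene switched on by ATF4 and CHOP, rose from 7.04 ± 0.646 to 46.0 ± 4.83 FPKM, a log2 change of 2.55 ± 0.10 (adjusted p = 3.06e-05). Thbs1, which encodes the matrix glycoprotein thrombospondin 1, fell from 49.2 ± 4.64 to 10.3 ± 1.5 FPKM, a log2 change of -2.16 ± 0.11 (adjusted p = 0.000121). Col1a2, a chain of type I collagen, fell from 22.1 ± 1.26 to 6.55 ± 0.800 FPKM, a log2 change of -1.62 ± 0.09 (adjusted p = 0.000132). In the mm10 build the exons and introns of Hmox1 span chromosome 8 from 75093621 to 75100589, those of Trib3 chromosome 2 from 152337422 to 152344032, those of Thbs1 chromosome 2 from 118111876 to 118127133, and those of Col1a2 chromosome 6 from 4504814 to 4541544. All 4 are annotated as protein-coding.

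Of 11068 genes tested, 3938 passed an adjusted p of 0.05, 2128 higher and 1810 lower in Light. Changes of at least 2-fold were rarer, with 84 genes higher and 164 lower. The 3 Light values lay wholly above or below the 3 Dark values for 5822 genes (52.6%), where chance gives 10% for a single gene. Genes vary together between libraries, so the share over genes cannot be weighed against that figure. The split by direction depended on scaling: with every library rescaled to the same FPKM total, a choice made after the data were seen, 1212 genes were higher and 2902 lower, and the median change over all genes moved from -0.01 to -0.13. The number of called genes also depended on the libraries kept, at 1277 without Dark 3, 1313 without Light 2 and 1228 without Light 3. All 3938 kept their direction in these fits, which leave 2 libraries in 1 group. A call lost there need not mean a smaller change. The number changed at least 2-fold was 165 without Dark 1, 458 without Dark 2 and 141 without Light 2.

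The largest increase belonged to Gsta1, a glutathione S-transferase gene, which stood at 0.490 ± 0.316 FPKM in Dark and 24.0 ± 2.54 in Light (log2 change 4.09 ± 0.16, adjusted p = 3.99e-05). Its assignment is uncertain, because the near-identical Gsta2 and Gm3776 rose with it, by 2.49 and 3.43. Gsta4, another glutathione S-transferase gene, rose by 2.68, and Aldh3a1, which encodes an aldehyde dehydrogenase, by 2.60. The cell cycle inhibitor gene Cdkn1a rose by 2.27, the stress cytokine gene Gdf15 by 2.20, the MAP kinase phosphatase gene Dusp4 by 2.19, the glycine transporter gene Slc6a9 by 1.98 and the glutathione-degrading enzyme gene Chac1 by 1.97. With Hmox1 and Trib3 these make up the 10 largest increases, whose adjusted p-values were at most 0.000327.

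Among the 10 largest decreases, Ogn, which encodes the small matrix proteoglycan osteoglycin, went furthest, from 17.7 ± 9.57 to 1.49 ± 0.679 FPKM (log2 change -2.82 ± 0.37, adjusted p = 0.00281). Abi3bp fell by 2.02 and Fmod, the gene of the proteoglycan fibromodulin, by 1.99. Medag fell by 1.90, Peg10, an imprinted gene of retrotransposon origin, by 1.84, and the hyaluronan synthase gene Has2 by 1.81. Nrep fell by 1.80 and Chrdl1, which encodes a BMP antagonist, by 1.71. Thbs1 is among the 10 too, and their adjusted p-values were at most 0.00536.

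**Figure D1:**
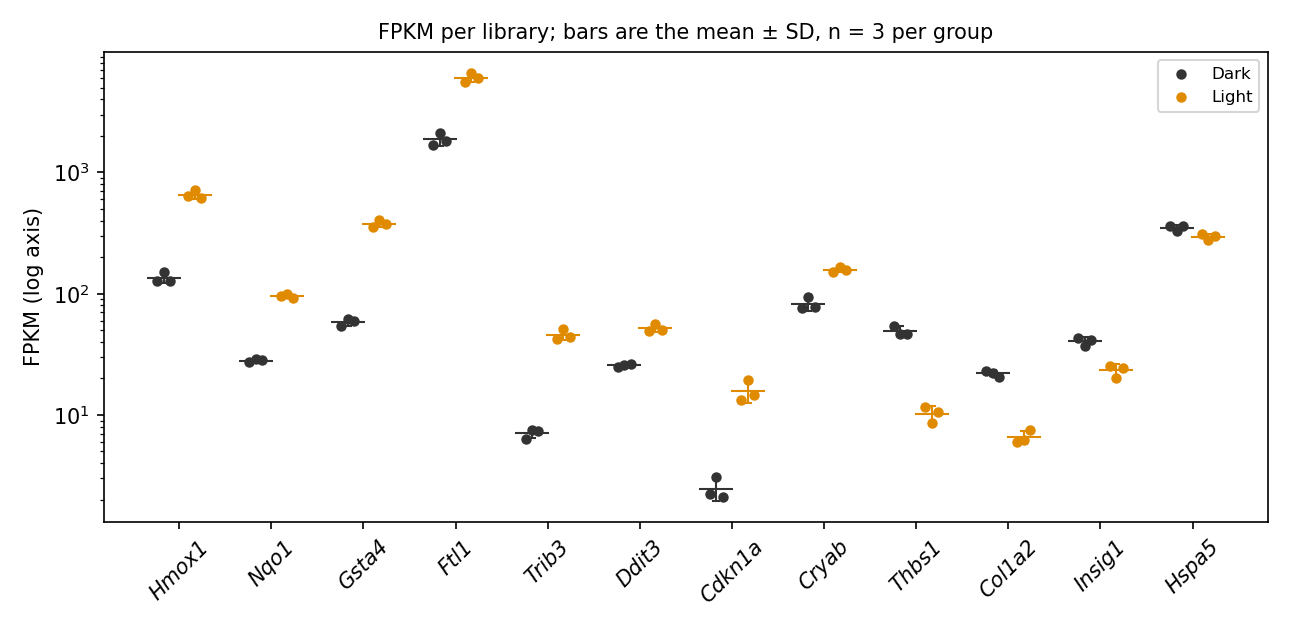
FPKM of 12 named genes on a log axis, with 1 point per library (black, Dark; orange, Light), a horizontal bar at the group mean and an error bar of 1 SD (n = 3 per group). Hmox1 stood at 135 in Dark and 656 in Light on average, Thbs1 at 49.2 and 10.3, and Hspa5 at 351 and 294.

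The libraries parted by group along the first principal component, which held 78.5% of the variance, but libraries of the same group also lay apart on it. Dark 1 stood at -36.5, Dark 3 at -20.9 and Dark 2 at -6.27, against 11 for Light 1, 20.9 for Light 3 and 31.7 for Light 2. Pearson correlations between libraries were 0.978 to 0.995 within groups and 0.939 to 0.984 between groups. Differences followed transcript length: the 10% of genes with the shortest transcripts had a median change of 0.23 in Light (408 genes higher, 37 lower), and the 10% with the longest a median of -0.37 (26 higher, 514 lower). Within groups, Dark 1 minus Dark 2 and Light 1 minus Light 2 had medians of -0.21 and -0.12 in the shortest 10% and of 0.23 and 0.21 in the longest. These 2 differences followed GC content more closely (Spearman rho -0.69 and -0.61) than length (0.38 and 0.41). In the 10% of genes with the lowest GC content their medians were 0.65 and 0.36, against -0.42 for Light minus Dark. Because of these trends, each called list is given with the median change of genes matched to it on transcript length, GC content and mean FPKM. Most other groups are given without it.

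**Figure D2:**
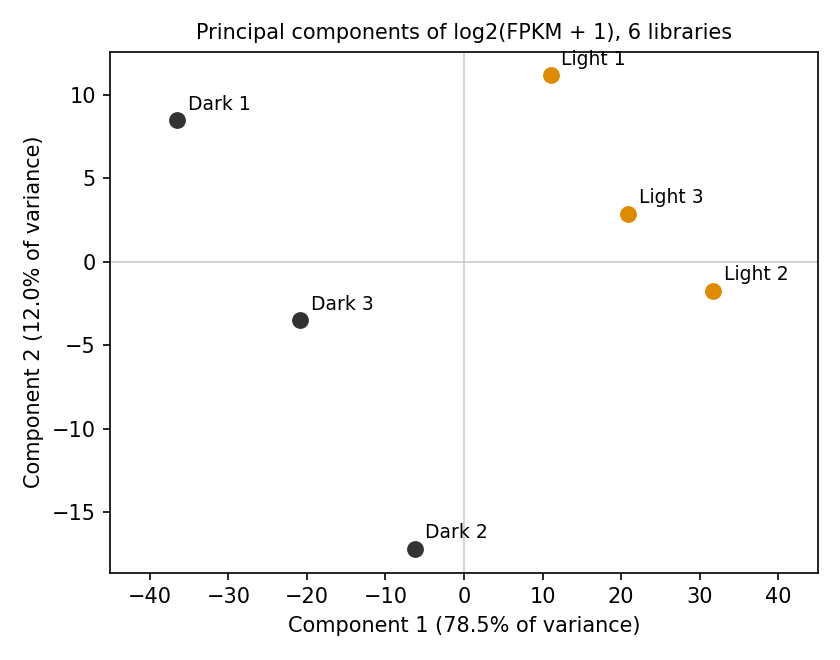
The 6 libraries on the first and second principal components (unitless scores) of log2(FPKM + 1), with 1 point per library. Component 1 holds 78.5% of the variance and parts Dark (black, -36.5 to -6.27) from Light (orange, 11 to 31.7), and component 2 holds 12%.

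**Figure D3:**
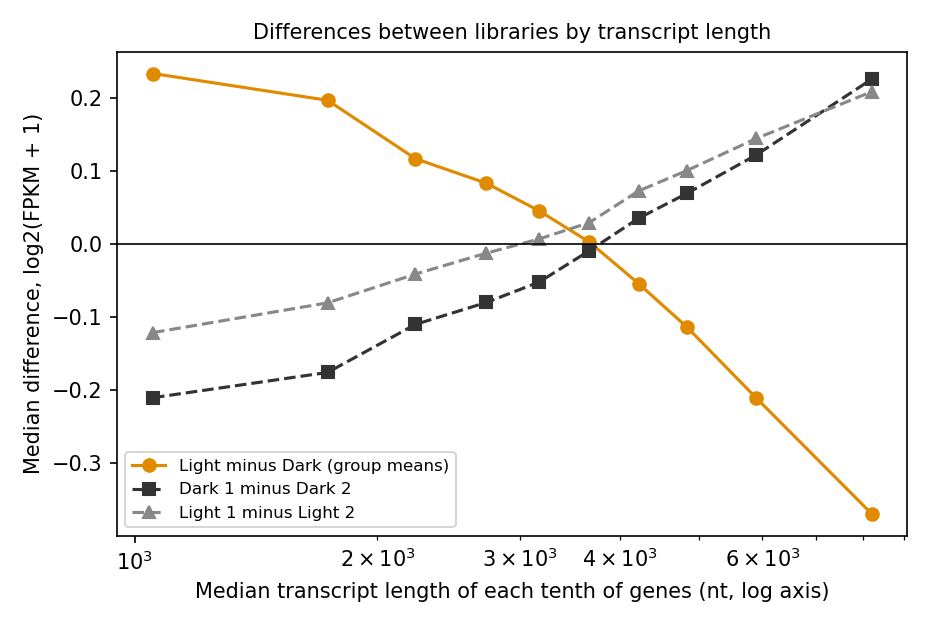
Median difference in log2(FPKM + 1), vertical axis, for each 10% of genes by transcript length in nucleotides, horizontal log axis, as Light minus Dark (circles), Dark 1 minus Dark 2 (squares) and Light 1 minus Light 2 (triangles). Light minus Dark runs from 0.23 in the shortest 10% to -0.37 in the longest, and both differences within a group run the other way.

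Gene lists were also tested as groups: 39 of the 45 had enough measured members, and camera with its preset correlation called 20, of which 14 were higher and 6 lower in Light. With an estimated correlation camera called 0 (lowest adjusted p = 0.221, 5 lists at an unadjusted p under 0.05), while fry, which asks only whether a list moves one way, called 28, among them 9 that camera did not. A list is said to be called where camera called it with the preset correlation. Regroupings of the 6 libraries that mixed Light with Dark, each of which keeps part of the difference between them, gave 10 to 18 called lists with the preset correlation. Some genes sit on more than 1 list, among them Slc7a11 on 3.

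Targets of NRF2, the transcription factor that answers oxidative and electrophilic stress, rose almost as a block. Of 23 measured members 22 rose, also when adjusted over the list alone, with a median log2 change of 0.88 (camera adjusted p = 1.77e-15; adjusted p = 0.221 with an estimated correlation), against 0.16 for matched genes. Nqo1, a quinone reductase gene, rose from 28.1 ± 0.744 to 95.9 ± 3.51 FPKM (log2 change 1.73 ± 0.06, adjusted p = 2.83e-05), as did Gsta4 and Gsta1. The exception was the thioredoxin gene Txn1, at 0.15 (adjusted p = 0.179). Among 19 other antioxidant enzymes 6 rose and 0 fell, the same when adjusted over the list alone, with a median of 0.23 against 0.15 for matched genes. Camera gave this list an adjusted p of 0.00392, and the adjusted p = 0.468 with an estimated correlation. Removing each library's trend with length and GC lowered its median to 0.07 and ended the call (adjusted p = 0.171). Its leading members were the peroxiredoxin gene Prdx6 (0.64), the superoxide dismutase gene Sod1 (0.59) and the catalase gene Cat (0.46). Mt1 and Mt2, metal-binding metallothionein genes, rose by 1.06 and 1.21, but their list of 5 was not called (2 higher, 1 lower, the same when adjusted over the list alone; median 0.16, adjusted p = 0.219), except with the length and GC correction (0.0498) and by fry (0.000210), in a range of 0.000210 to 0.468.

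Genes of iron handling and ferroptosis, the iron-dependent death through lipid peroxidation, moved both ways. Of 15 members 7 rose and 2 fell (8 and 2 when adjusted over the list alone), with a median of 0.42 against -0.02 for matched genes (camera adjusted p = 0.0193; adjusted p = 0.221 with an estimated correlation). The ferritin light chain gene Ftl1 rose from 1872 ± 233 to 6061 ± 525 FPKM (log2 change 1.70 ± 0.12, adjusted p = 0.000270). Its processed copy Ftl1-ps1 rose by 1.75, from 19.8 to 31.7 FPKM in the Dark libraries to 83.8 to 101 in Light. Reads shared between them leave the change of the copy uncertain, but the copy is too low to account for the rise of Ftl1. The iron reductase gene Steap3 rose by 0.92, and Chac1 is a member too. Gpx4, which encodes the peroxidase that repairs oxidised lipids, rose by 0.54 (adjusted p = 0.0166), a call lost without Dark 3 (0.0685), Light 2 (0.0704) or Light 3 (0.0663). The change of Gpx4 was 0.22 to 0.64 over its alternatives. Acsl4, which loads polyunsaturated fatty acids into lipids, fell by 1.18, and the iron regulatory gene Ireb2 fell by 0.75. The list's call was lost without Dark 2 (adjusted p = 0.0530) and among genes with a mean of at least 5 FPKM (median 0.14, adjusted p = 0.137). Over its alternatives the adjusted p ran from 0.000210 to 0.221.

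The integrated stress response, in which ATF4 raises genes of amino acid supply, rose as completely as the NRF2 targets. Of 25 members 24 rose, the same when adjusted over the list alone, with a median of 0.93 (camera adjusted p = 1.41e-16; adjusted p = 0.221 with an estimated correlation) against 0.16 for matched genes. Atf4 itself rose from 155 ± 3.04 to 305 ± 7.23 FPKM (log2 change 0.97 ± 0.06, adjusted p = 0.000169), and Ddit3, the gene of the transcription factor CHOP, from 25.8 ± 0.658 to 51.9 ± 4.05 (0.98 ± 0.07, adjusted p = 0.000327). A second identifier named Ddit3 was listed at 0 in all libraries. Trib3, Chac1 and Gdf15 had the smallest p-values, and Cebpb, at 0.44, was the exception (adjusted p = 0.128). Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose in 15 of 18 cases, also when adjusted over the list alone, with a median of 0.47 against 0.09 for matched genes (camera adjusted p = 7.72e-08; adjusted p = 0.221 with an estimated correlation). Sars rose by 1.06, Cars by 0.74 and Nars by 0.58.

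Genes of the endoplasmic reticulum unfolded protein response, the targets of ATF6 and XBP1, fell more often than they rose. Of 23 members 9 fell, 1 rose and 13 were not called (11 lower and 1 higher when adjusted over the list alone), with a median of -0.19 (-0.33 to -0.13 over the alternatives) against 0.09 for matched genes (camera adjusted p = 0.0257; adjusted p = 0.221 with an estimated correlation). The riser was Herpud1, a gene of degradation at the reticulum, by 0.88. Pdia4, a disulphide isomerase gene, fell by 0.37 and Ssr1, a translocon gene with a long transcript, by 0.41. The call of Pdia4 was lost without Light 3 (adjusted p = 0.0567), and Ssr1 stood at 0.09 once each library's trend with length and GC was removed (adjusted p = 0.467). Hspa5, the gene of the reticulum chaperone BiP, stood at 351 ± 17.7 FPKM in Dark and 294 ± 15.0 in Light, a log2 change of -0.25 ± 0.07 (adjusted p = 0.0372). That call was lost without any one of Dark 1 (0.0714), Dark 3 (0.131), Light 1 (0.0525), Light 2 (0.138) or Light 3 (0.117), and with median centring (0.0985). The list's own call was lost without Dark 2 (adjusted p = 0.0530) and with median centring (0.0548), within a range of 0.000155 to 0.221 over its alternatives.

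Lysosomal genes rose in 22 of 27 cases (23 when adjusted over the list alone), with a median of 0.39 (0.24 to 0.44 over the alternatives) against 0.12 for matched genes. The camera adjusted p was 3.48e-08, and the adjusted p = 0.221 with an estimated correlation. The glycosidase gene Gla rose by 0.99, Hexa, a subunit of hexosaminidase, by 0.81 and the carboxypeptidase gene Ctsa by 0.73. Of 27 autophagy genes 12 rose and 1 fell (12 and 3 when adjusted over the list alone). Their median was 0.20 (0.07 to 0.28 over the alternatives) against 0.04 for matched genes. The camera adjusted p was 0.0201, and the adjusted p = 0.442 with an estimated correlation. Sqstm1, the gene of the cargo receptor p62, rose from 277 ± 31.6 to 735 ± 80.8 FPKM (1.40 ± 0.11, adjusted p = 0.000425), Gabarapl1 by 0.77 and Map1lc3b by 0.58, while Atg3 fell by 0.35. Proteasome subunit genes rose in 22 of 31 cases (24 when adjusted over the list alone), with a median of 0.34 (0.17 to 0.40 over the alternatives) against 0.18 for matched genes, a camera adjusted p of 2.16e-07 and an adjusted p = 0.221 with an estimated correlation. Psmb3 rose by 0.64, Psmd11 by 0.37 and Psma5 by 0.34.

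Heat shock genes, which encode mostly chaperones, rose in 12 of 20 cases and 0 fell, the same when adjusted over the list alone. Their median was 0.36 (0.21 to 0.41 over the alternatives) against 0.12 for matched genes, with a camera adjusted p of 0.00139 and an adjusted p = 0.221 with an estimated correlation. The small heat shock protein genes Cryab and Hspb8 rose by 0.93 and 0.79, and Hspa1b, a gene of inducible HSP70, by 0.49. Its neighbour Hspa1a, near-identical in sequence and therefore uncertain, rose by 0.61 (adjusted p = 0.0219). The call of Hspa1a was lost without Dark 3 (0.0740), Light 2 (0.0852) or Light 3 (0.0653). Genes of mitochondrial quality control and the mitochondrial unfolded protein response were not called as a list (8 of 17 higher, 2 lower, the same when adjusted over the list alone; median 0.13, adjusted p = 0.23), but fry called it higher (0.00261; range 0.00261 to 0.526). Among them the protease gene Lonp1 rose by 0.65 and the chaperone gene Hspa9 by 0.57.

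Of 43 cytosolic ribosomal protein genes 34 rose, 9 were not called and 0 fell (37 higher and 0 lower when adjusted over the list alone), with a median of 0.45, and matched genes, which share their short transcripts, had 0.26. The camera adjusted p was 1.56e-09, and the adjusted p = 0.468 with an estimated correlation. The median was 0.18 to 0.53 over the alternatives. Rpl19 rose by 0.63, Rps9 by 0.53 and Rps4x by 0.38. These changes moved little when 1 library was left out, at 0.63, 0.54 and 0.36 without Dark 3 and 0.63, 0.53 and 0.38 without Light 3. Their calls were lost without Dark 3 (adjusted p = 0.0504 for Rpl19, 0.0505 for Rps9, 0.0614 for Rps4x) and without Light 3 (0.0508, 0.0545 and 0.0592), and those of Rps9 and Rps4x also without Light 2 (0.0529 and 0.0520). Quantile normalization lowered the change of Rps4x to 0.10 and ended its call as well (adjusted p = 0.140). Ribosome biogenesis genes rose in 12 of 27 cases with 0 lower, the same when adjusted over the list alone, with a median of 0.22 (0.10 to 0.28 over the alternatives) against 0.10 for matched genes. Their camera adjusted p was 0.00392, and the adjusted p = 0.221 with an estimated correlation. Nhp2, of the box H/ACA ribonucleoproteins, rose by 0.69, Mybbp1a by 0.47 and the RNA polymerase I subunit gene Polr1b by 0.41.

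Nuclear genes of oxidative phosphorylation rose no further than genes of like length, GC content and level. Of 35 members 8 rose and 0 fell (6 and 0 when adjusted over the list alone), with a median of 0.21, and matched genes had 0.20 (list at percentile 61.6 of the matched draws). Camera gave an adjusted p of 0.000545, and the adjusted p = 0.535 with an estimated correlation. The call was lost with quantile normalization (median 0.05, adjusted p = 0.542) and with the length and GC correction (median 0.05, adjusted p = 0.469), fry gave 0.0688, and without Dark 1 the median was 0.11. Atp5g1 rose by 0.42 (0.24 to 0.58 over its alternatives), the succinate dehydrogenase gene Sdhb by 0.40 (0.15 to 0.48) and the complex I gene Ndufc2 by 0.30. Calls of all 3 were lost without Dark 3 (adjusted p = 0.0700, 0.0735 and 0.0894), Light 2 (0.0825, 0.0810 and 0.104) or Light 3 (0.0634, 0.0760 and 0.0924), and that of Ndufc2 also without Dark 1 (0.0561), with the length and GC correction (change 0.11, adjusted p = 0.132) and with TPM rescaling (0.16, 0.0747), in a range of 3.29e-05 to 0.161. The 13 mitochondrially encoded genes were not called as a list (1 higher, 3 lower, the same when adjusted over the list alone; median -0.43, adjusted p = 0.0667), but were under 6 of 18 alternatives, among them without Light 1 (median -0.67, adjusted p = 0.00527). The others were quantile normalization (-0.73, 0.000815), the replicate number as a block (0.0141), the within-group axis as a covariate (0.0232), a mean of at least 5 FPKM (0.0332) and median centring (0.0463), in a range of 0.000815 to 0.659. Taking out the slope of all genes' changes on the difference within groups left the median at 0.08. The cytochrome oxidase gene mt-Co1 fell by 0.72 and the complex I gene mt-Nd3 rose by 0.57, a call lost with quantile normalization (0.31, adjusted p = 0.0644; range 0.000848 to 0.0644). Mitochondrially encoded transcripts made up 6.11 ± 0.870% of all FPKM in Dark and 4.32 ± 1.14% in Light (SD, n = 3).

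Fibroblast and mesenchymal markers fell without exception among those measured. All 13 fell, also when adjusted over the list alone, with a median of -0.83 against 0.05 for matched genes (camera adjusted p = 1.86e-10; adjusted p = 0.221 with an estimated correlation). Col3a1, a fibrillar collagen gene, fell from 62.4 ± 4.59 to 23.2 ± 1.24 FPKM (log2 change -1.39 ± 0.08, adjusted p = 0.000124), as did Col1a2, and Col5a2 fell by 0.89. Of 27 extracellular matrix genes and TGF-beta targets, 6 of them shared with the fibroblast list, 18 fell and 1 rose (19 and 3 when adjusted over the list alone), with a median of -0.62 against 0.05 for matched genes. The camera adjusted p was 9.18e-07, and the adjusted p = 0.241 with an estimated correlation. Targets of YAP and SRF, which answer adhesion and tension, fell in 8 of 15 cases and rose in 1 (9 and 2 when adjusted over the list alone), with a median of -0.33 against 0.08 for matched genes. Their camera adjusted p was 0.00392, and the adjusted p = 0.468 with an estimated correlation. With no filter on low values their median was -0.18. Ctgf, which encodes a matricellular growth factor, fell by 1.57, the smooth muscle actin gene Acta2 by 0.84 and Amotl2 by 0.77, while the receptor kinase gene Axl rose by 0.21.

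Cholesterol synthesis genes, the targets of SREBP2, fell in 15 of 23 cases and rose in 2, the same when adjusted over the list alone. Their median was -0.36 against 0.05 for matched genes, with a camera adjusted p of 0.000453 and an adjusted p = 0.318 with an estimated correlation. Hmgcs1, which encodes the synthase before HMG-CoA reductase, fell from 38.1 ± 7.16 to 16 ± 2.25 FPKM (log2 change -1.19 ± 0.15, adjusted p = 0.00232), Hsd17b7 by 0.94 and Insig1, a sterol-sensing regulator, by 0.78. The risers were Mvd by 0.43 and Ebp by 0.25. Fatty acid synthesis genes were not called as a list (6 of 15 lower, 2 higher, the same when adjusted over the list alone; median -0.13, adjusted p = 0.136), except under 4 of 18 alternatives (adjusted p of 0.0168 to 0.533 over all), although the desaturase genes Scd1 and Scd2 fell by 0.76 and 0.49.

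Interferon-stimulated genes fell in 9 of 24 cases and rose in 1 (10 and 2 when adjusted over the list alone), with a median of -0.25 against 0.05 for matched genes (camera adjusted p = 0.0214; adjusted p = 0.413 with an estimated correlation). Oasl2 fell by 0.72, the guanylate-binding protein gene Gbp3 by 0.60 and Ddx58, which encodes the RNA sensor RIG-I, by 0.43. Bst2, the gene of tetherin, rose by 0.49. The list's call was lost without Dark 2 (adjusted p = 0.0866), with quantile normalization (0.0838), and among genes with a mean of at least 5 FPKM (median -0.03, adjusted p = 0.263). It was also lost with the replicate number as a block (0.0502) and with the within-group axis as a covariate (0.0624), in a range of 0.000257 to 0.413 over its alternatives. The call of Gbp3 was lost without Dark 3 (adjusted p = 0.0538). NF-kB and cytokine genes were not called (7 of 20 lower, 3 higher; 7 and 5 when adjusted over the list alone; median -0.02, adjusted p = 0.455), but fry called them lower (0.0192; range 0.0192 to 0.772). The adhesion molecule gene Vcam1 fell by 1.46 and the chemokine gene Cxcl10 by 0.98, whereas Ccl2 stood at 0.23 ± 0.19 (adjusted p = 0.349), but passed with the replicate number as a block (0.0145) and with the within-group axis as a covariate (0.00324), in a range of 0.00324 to 0.939. Complement genes were not called (4 of 8 lower, 1 higher, the same when adjusted over the list alone; median -0.32, adjusted p = 0.123), but were under 5 of 18 alternatives, among them without Dark 1 (adjusted p = 0.0488) and with the length and GC correction (0.0266), in a range of 0.0266 to 0.535. The complement gene C3 fell by 0.95. MHC class I and antigen presentation genes were not called (3 of 14 higher, 0 lower; 1 and 0 when adjusted over the list alone; median 0.09, adjusted p = 0.23). H2-D1 rose by 0.43 (0.20 to 0.50 over its alternatives), a call lost without Dark 3 (0.0686), Light 2 (0.0680) or Light 3 (0.0580). Psme1 rose by 0.25, a call lost without Dark 1 (0.0966), Dark 3 (0.124), Light 1 (0.0904), Light 2 (0.133) or Light 3 (0.127). The change of Psme1 was 0.03 with the length and GC correction (adjusted p = 0.671), 0.10 with quantile normalization (0.167) and 0.10 with TPM rescaling (0.188), and its call was also lost with median centring (0.0542), in a range of 0.000359 to 0.671.

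Targets of p53, which responds to DNA damage and other stress, rose in 10 of 22 cases and fell in 2 (11 and 2 when adjusted over the list alone), with a median of 0.24 (0.13 to 0.53 over the alternatives) against 0.02 for matched genes. The camera adjusted p was 0.0323, and the adjusted p = 0.221 with an estimated correlation. Cdkn1a stood at 2.47 ± 0.510 FPKM in Dark and 15.8 ± 3.35 in Light (log2 change 2.27 ± 0.16, adjusted p = 0.000327). Sesn2, which is also an ATF4 target, rose by 1.00, and its relative Sesn1 fell by 0.77. Fas, a death receptor gene, fell by 0.39. The list's call was lost without Dark 2 (adjusted p = 0.133), with the replicate number as a block (0.0502) and with the within-group axis as a covariate (0.0863), in a range of 0.000721 to 0.221. Apoptosis regulators and caspases were not called (4 of 25 higher, 2 lower; 3 and 2 when adjusted over the list alone; median 0.04, mean -0.05, adjusted p = 0.917). The BH3 genes Bid and Bcl2l11 parted, by 0.58 up and by -0.74. Necroptosis and pyroptosis genes were not called (4 of 11 higher, 1 lower, the same when adjusted over the list alone; median 0.07, adjusted p = 0.23), but fry called them higher (0.0107; range 0.0107 to 0.468), and the pore-forming gasdermin gene Gsdme rose by 0.86 and the kinase gene Ripk3 by 0.58.

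Of 30 genes that act in mitosis 7 fell and 0 rose (1 and 0 when adjusted over the list alone), with a median of -0.11 and an adjusted p of 0.0542, and the list was called without Dark 1 (0.0409), Dark 2 (0.0323) or Light 3 (0.0306). It was also called with quantile normalization (0.000155), TPM rescaling (0.00724), the length and GC correction (0.0151), the within-group axis as a covariate (0.0152), the replicate number as a block (0.0170) and a mean of at least 5 FPKM (0.0292), in a range of 0.000155 to 0.492 over its alternatives. Mki67, the proliferation marker, has one of the longest transcripts of the list and fell from 30.2 ± 11.1 to 9.99 ± 2.14 FPKM (log2 change -1.47 ± 0.26, adjusted p = 0.00826). The cyclin gene Ccna2 fell by 0.48, a call lost without Dark 3 (0.0748), Light 2 (0.0764) or Light 3 (0.0694), whereas Cdk1 stood at 0.05 (adjusted p = 0.517) and Ccnb1 at -0.02 (0.817). Across the 30 genes the change ran against the difference between libraries of the same group (Spearman rho -0.90). Replication genes were not called (5 of 29 higher, 2 lower, the same when adjusted over the list alone; median 0.04, mean -0.0024, adjusted p = 0.525). Chaf1b rose by 0.41 and Mcm4 fell by 0.37, both calls lost without Dark 3 (0.0618 and 0.0655), Light 2 (0.0579 and 0.0739) or Light 3 (0.0592 and 0.0683). DNA repair genes were not called (5 of 30 higher, 1 lower; 4 and 0 when adjusted over the list alone; adjusted p = 0.939), and their median of -0.07 differs in sign from the direction camera gave. Of these the base excision repair genes Apex1 and Ogg1 rose by 0.53 and 0.51, the call of Ogg1 being lost without Dark 3 (0.0545), Light 2 (0.0647) or Light 3 (0.0665). Replication-dependent histone genes were not called (1 of 7 lower, also when adjusted over the list alone; median -0.21, adjusted p = 0.126), but were under 4 of 18 alternatives, among them without Dark 1 (0.0409), without Light 2 (0.0379) and with the length and GC correction (0.00424), in a range of 0.00424 to 0.471.

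Immediate early genes, the first to respond to many stimuli, rose in 12 of 22 cases and fell in 2 (13 and 2 when adjusted over the list alone), with a median of 0.30 (0.19 to 0.37 over the alternatives) against 0.16 for matched genes. The camera adjusted p was 0.00128, and the adjusted p = 0.221 with an estimated correlation. Ier3 rose from 51.2 ± 2.76 to 163 ± 7.94 FPKM (log2 change 1.65 ± 0.07, adjusted p = 4.13e-05), Atf3 by 1.34 and the AP-1 gene Fosl1 by 0.98. The AP-1 gene Fos went the other way, at -0.78 ± 0.22 (adjusted p = 0.0336), a call lost without Dark 1 (0.0700), Dark 3 (0.0689), Light 2 (0.0842) or Light 3 (0.0929), and Egr1 fell by 0.80. Circadian clock genes were not called (4 of 16 higher, 2 lower, the same when adjusted over the list alone; median -0.03, mean 0.05, adjusted p = 0.554), but fry called them higher (0.000389; range 0.000389 to 0.874). The clock repressor gene Nr1d1 rose by 0.70, while the light-inducible clock gene Per1 stood at 0.18 ± 0.08 (adjusted p = 0.131), and passed only with the within-group axis as a covariate among its alternatives (0.0339; range 0.0339 to 0.634). Hypoxia genes were not called (4 of 18 higher, 6 lower, the same when adjusted over the list alone; median 0.07, adjusted p = 0.757), but fry called them higher (0.0349; range 0.0349 to 0.967), and Ndrg1 rose by 1.70 and the vascular growth factor gene Vegfa by 0.93. Glycolysis genes were not called (6 of 21 higher, 1 lower, the same when adjusted over the list alone; median 0.25, adjusted p = 0.106), but were without Dark 2 (0.0296) and with the within-group axis as a covariate (0.0309), in a range of 0.0296 to 0.899. The phosphofructokinase gene Pfkp rose by 0.40, a call lost without Light 3 (0.0508), and the regulator gene Pfkfb3 fell by 0.60.

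Cone opsin and transducin transcripts were low or listed at 0 in both groups. Opn1mw, the green cone opsin gene, was listed at 0 in all 6 libraries, the blue cone opsin gene Opn1sw lay between 0.0283 and 0.166 FPKM, and the cone transducin gene Gnat2 between 0.633 and 1.2, so none of them was tested. Only 1 of 18 cone phototransduction genes in the table reached the mean of 1 FPKM needed for testing, Rgs9 not being called. Of 3 tested rod phototransduction genes 0 were called (0 also when adjusted over the list alone; median 0.13, adjusted p = 0.323 for the list by camera), while fry called the list higher (0.00261; range 0.00261 to 0.531). Of 3 tested genes of photoreceptor transcription and the visual cycle, the retinol dehydrogenase gene Rdh5 rose by 0.32 and Rdh10 fell by 0.39, the same when adjusted over the list alone (adjusted p = 0.89 for the list). The cryptochrome genes Cry1 and Cry2, the 2 light-sensing genes of 10 that were tested, stood at -0.02 and -0.07 (adjusted p = 0.872 and 0.556). Of 6 tested markers of Mueller glia and astrocytes, Glul fell by 0.58 and Slc1a3 by 0.67, the same 2 when adjusted over the list alone (list median 0.02, mean -0.10, adjusted p = 0.573). Markers of other retinal cells were too few at this level for a list test. Of 14 microglial and macrophage markers only Cd68 was tested, and it rose by 1.02. Of 11 endothelial markers 2 were tested and Flt1 fell by 0.59, and of 15 retinal ganglion cell and 12 pigment epithelium markers 1 each was tested and 0 were called. With no filter on low values the 6 lists too small to test had adjusted p-values of 0.435 to 0.999.

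**Figure D4:**
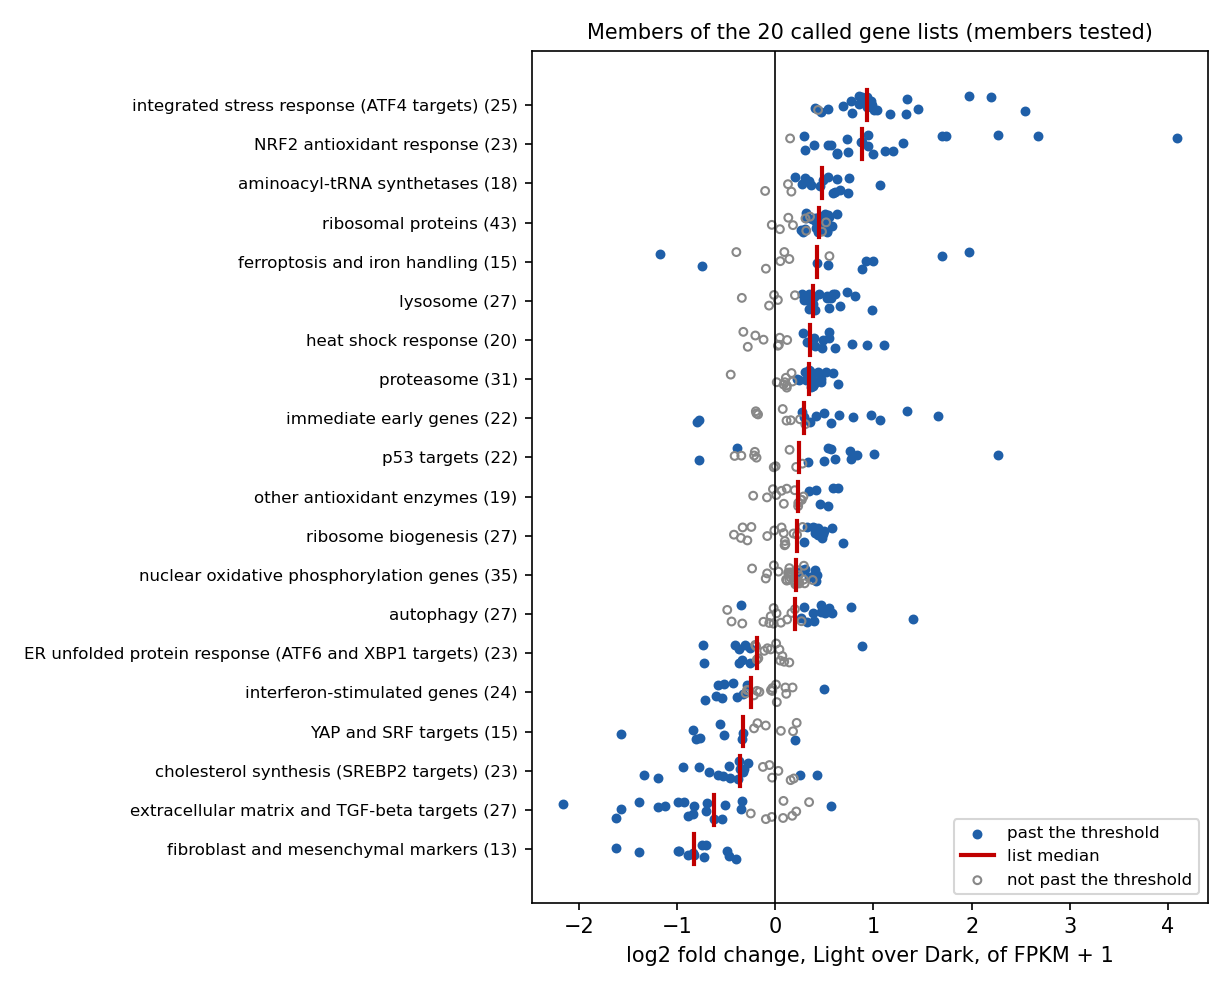
Log2 fold change, Light over Dark, of FPKM + 1 (horizontal axis) for the measured members of the 20 called gene lists, with the number of members in brackets, filled points past an adjusted p of 0.05, open points not past it, and a red bar at the list median. Medians run from 0.93 for the ATF4 targets to -0.83 for the fibroblast markers.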

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

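The TPM rescaling, the length and GC correction, the covariate of differences within groups and the fit without Dark 1 and Light 2 were tests chosen only after the results were seen. Against 3938 called genes, 2606 were called with no filter on low values (19300 genes tested), 7242 with the within-group covariate and 1427 without Dark 1 and Light 2, and leaving out 1 library gave 1228 to 5874. The replicate number as a block gave 6690. Deviations from the group means correlated at 0.687 and 0.641 for numbers 1 and 2, and at -0.089 for number 3. Dark 3 deviated most like Light 2 (0.043) and Light 3 most like Dark 2 (0.077). On the first principal component Dark 3 (-20.9) and Light 3 (20.9) lay near the middle of their groups, which leaves little deviation to correlate. The values for number 3 therefore cannot decide whether equal numbers share a batch, which the labels do not record. The block ended the list calls of the p53 targets and the interferon-stimulated genes and added those of mitosis and the mitochondrially encoded genes. Against 248 genes changed at least 2-fold, 444 were called with a pseudocount of 0.1, 140 with the length and GC correction and 126 without Dark 1 and Light 2, and leaving out 1 library gave 141 to 458. Fewer samples, fewer genes or a smaller pseudocount are part of these alternatives' own construction, and otherwise the cause was not tested. All 3938 called genes kept their direction in every alternative that tested them, except under quantile normalization (3930 of 3938) and the length and GC correction (3697 of 3839). The filters on low values, the replicate block and the within-group covariate leave fold changes as they are, so they could not change a direction. Among the genes that the naming rule gives only Ssr1 changed direction, and genes named outside the rule were not followed singly. It went to 0.0898 with the length and GC correction, and the cause was not tested. With no filter 7 named genes lost their call (Atp5g1, Ccna2, Fos, Hspa1a, Hspa5, Ndufc2 and Psme1), and without Dark 1 and Light 2 these 7 and 10 more did (Chaf1b, Gbp3, Gpx4, H2-D1, Mcm4, Ogg1, Pdia4, Pfkp, Psma5 and Sdhb). Against 20 called lists, camera with an estimated correlation called 0, of which the cause was not tested, while fry called 28 and the other alternatives 18 to 23. DESeq2, limma-voom and glmTreat were planned for counts only and not run. Depth is unknown, so its effect on low genes was not assessed.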

Other observations

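The tests of gene families by symbol, the length and GC correction, the slope on the within-group direction and the comparison of shorter with longer mitosis genes were chosen only after the results were seen. Families are genes that share a symbol stem, and the families and members named here were picked after their values were seen. Of 324 families with at least 5 tested members camera called 15 with the preset correlation, and with an estimated correlation each of these 15 had an adjusted p of 0.940. Genes with the stem Col fell in 14 of 18 cases (median -0.85). Of the 18, 9 are on fixed lists, and Col4a3bp is a collagen by symbol only. Col12a1 fell by 1.65 and Col8a1 by 1.21. Secreted metalloproteinases of the Adamts family, which trim matrix proteins, fell in 7 of 9 cases (median -0.63), with Adamts2 at -1.03. Frizzled receptor genes, which receive Wnt signals, fell in 5 of 8 cases (median -0.47), with Fzd7 at -1.04.

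Mitochondrial ribosomal protein genes rose in 28 of 49 cases for the large subunit, with 1 lower (median 0.33, matched genes 0.15), and in 14 of 29 for the small subunit, with 0 lower (median 0.28, matched genes 0.14). Of 11 genes with the stem Eef 8 rose (median 0.41), the elongation factor genes Eef1a1 (0.40), Eef1b2, Eef1g and Eef2 and 4 genes of enzymes that modify such factors. Genes of the aldehyde dehydrogenase family rose in 8 of 12 cases (median 0.26), with Aldh1l2, a mitochondrial folate enzyme, at 1.26. Genes with a CHCHD motif rose in 6 of 8 cases (median 0.42), with Chchd10 at 1.79. These medians had the same sign under TPM rescaling, quantile normalization and median centring. Gapdh, a glycolysis gene often used as a reference, was listed at 38.7 to 48.3 FPKM in 5 libraries and 146 in Light 2, while Eno1 and Pkm stood at 739 to 1811.

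Dark 1 departed from Dark 2 in the same direction as Light 1 from Light 2 (Pearson r = 0.75 across 10664 genes, which are not independent replicates), and Light minus Dark ran the opposite way (r = -0.66). With the slope on this direction taken out, the list median was 0.82 for ATF4 targets, 0.75 for NRF2 targets and -0.65 for matrix genes. It was lower for ribosomal proteins (0.22, from 0.45) and the proteasome (0.21, from 0.34). Little was left for other antioxidant enzymes (0.05, from 0.23) and nuclear oxidative phosphorylation (0.03, from 0.21). Ribosomal protein genes also differed within groups, with medians of -0.33 (Dark 1 minus Dark 2) and -0.19 (Light 1 minus Light 2). A trend with transcript length and GC content may be part of this, but after each library's trend was removed the correlation was still 0.54. Length and GC content of the longest annotated transcript may differ from those of the expressed one, so the trend may have been removed only in part. The test therefore cannot decide whether the trend is the whole cause. Differences in RNA integrity, library preparation or culture density stay open, since the labels record none of them. No biological explanation was tested.

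Transcript length and GC content could also account for list changes, because short transcripts and GC-rich transcripts were higher in Light. Against genes matched on length, GC content and mean FPKM, the median of the list differed by 0.18 for ribosomal proteins, 0.16 for the proteasome, 0.77 for ATF4 targets, 0.72 for NRF2 targets and -0.67 for extracellular matrix genes. The first 4 lists lay above at least 99.97% of the matched draws and the matrix genes below all of them. That argues against length and GC of the longest annotated transcript as the whole cause, but the expressed transcripts may differ from it. The draws also treat members as independent, although ribosomal protein genes had an estimated correlation of 0.75, so these percentiles overstate the certainty. The matched genes' own medians, 0.26 for ribosomal proteins and 0.18 for the proteasome, are more than the excess. Part of both rises may therefore come from the trend. Genes of the same families outside the lists could serve as matches, so these medians need not reflect the trend alone. A response to the lamp stays open as a hypothesis, beside any difference in handling between the groups that the labels do not record.

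Of the 7 mitosis genes that fell, 5 have transcripts longer than the list's median length, Mki67, Cenpf and Cenpe among them, and 2 have shorter ones. Other members with longer transcripts did not fall, such as Cdk1 (0.05). Across the 30 genes the change ran against the direction in which libraries of the same group differ (Spearman rho -0.90; permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted 2e-05 over 2 tests, across genes that are not independent replicates), and against transcript length (rho -0.57; permutation p = 0.0011). That direction may therefore contribute: taking out its slope left Mki67 at -0.76 and the list's median at -0.01, while the length and GC correction left Mki67 at -1.01 and 14 of the 30 genes lower. Fewer dividing cells could not be told apart from it. The 15 members with shorter transcripts had a median of -0.026 (SD 0.27) and 0.03 with median centring, but -0.13 with quantile normalization, -0.16 with TPM rescaling (all genes -0.13) and -0.16 with the length and GC correction, so the result depends on the setting. The longer members had a median of -0.30, and of -0.11 with the length and GC correction.

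The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. Only 1 of the 10 splits, the real one, gave as many called genes, with 3938 against 0 at most in the others (limma; 22 to 2018 genes at an unadjusted p under 0.05), and the same holds for genes changed at least 2-fold, with 248 against 0. For called lists the real split gave 20 and the highest other 18. Each other split puts Light and Dark libraries in the same arm. Their difference then adds to the spread within arms, which lowers gene calls, so the counts of 0 cannot weigh against chance. Part of the difference also stays between the arms, so the list calls of these splits were not separated from it. In each of the 20 called lists the median lay further from 0 in the real split than in any other. These lists were called on the real split, and the other splits hold only part of the difference. That order was therefore largely fixed in advance.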
